A study of Mus musculus with 2 samples.

How the data were processed

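Tongues of mouse embryos at embryonic day 12, on a mixed background, were dissected and frozen, and total RNA was extracted with a Qiagen RNeasy micro kit, per the labels' protocols. Per the series' design text, RNA was extracted from pools made of 3 pairs, a pair being a control and a mutant sample. The cDNA was made with the NuGEN Ovation RNA-Seq v2 system, which amplifies RNA from small samples. The groups were taken from the genotype labels, with 1 control library (Osr1f/+) and 1 mutant library (Osr1f/-; Wnt1cre).

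The submitters' processing notes name Bowtie 0.12.7, TopHat 1.4.1 and the mouse build mm9. Per the file headers, the deposited FPKM values are per RefSeq transcript and locus, in a table laid out as a Cufflinks isoform table. The Cufflinks version, the read length and the strand setting are not given in the sources used here. FPKM is a number of fragments scaled by the length of the transcript and by the mapped fragments of the library. A second deposited column, per the file headers, holds the coverage of each transcript, a signal that is not scaled for depth. Per the file headers, each row also has a status, which was OK for 27768 rows of the control and 27782 rows of the mutant library. It was LOWDATA for 294 rows in each library and FAIL for 45 and 31. The files gave no interval of the FPKM and no read counts. The authors' tool shared reads among overlapping transcripts by estimation, so values of overlapping or near-identical genes are uncertain. Besides those pointed out with their values, the named genes Col9a3, Matn4, Ogn, Scx, Itga4, Hoxa3, Gli1, Boc, Shh, Cdc20, Xist, Runx2 and Dlx6 overlap another gene model. Coordinates are given on mm9 as in the files, counted from 1. The reference annotation at hand was of another build and was not used for coordinates.

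Rows with the same symbol were summed to 22072 symbols. A gene was measured if its FPKM was at least 1 in either library and all of its rows had the status OK in both. This left 12383 genes and removed 204 symbols for their status, of which 96 had at least 1 FPKM. The FPKM summed to 305841 in the control and 305019 in the mutant library, and the 10 most abundant genes held 5.04% and 5.01% of the sum. At least 1 FPKM was reached by 12250 symbols in the control and 12297 in the mutant library. The log2 ratio was that of mutant FPKM plus 1 over control FPKM plus 1, which understates the difference of genes with low values, while plain ratios are of the FPKM. The deposited scale was kept, and setting the median log2 ratio to 0 would have moved it by 0.00296.

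Depth was estimated from the files. Coverage per FPKM was 0.894 in the control and 1.09 in the mutant library, so the mutant library was 1.22 times deeper. In genes of a single row of at least 1000 nt, the lowest products of coverage and length clustered at 47.4 bases, taken as 1 read. Dividing by this step gave about 18900000 and 23100000 mapped reads as the total behind the FPKM scale, and an approximate number of reads for each gene. From these reads the exact conditional (Clopper-Pearson) 95% interval of each ratio was computed. In genes of several transcripts the ratio of reads can differ from the ratio of FPKM. Intervals and floors cover counting error only, since amplified reads are not independent molecules, and they compare libraries and not genotypes. They hold no variation between embryos. The floor of a value was set at 3 reads.

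Which items the text names followed a rule fixed before the data were examined. It took Osr1 and Osr2, the 12 genes with the largest higher and the 12 with the largest lower log2 ratio among genes with at least 5 FPKM in either library, and up to 4 members of each list by the size of the log2 ratio at 5 FPKM. Sex-linked genes, and symbols that by their first or last letters are unnamed models, microRNAs or small nucleolar or nuclear RNAs, were left out of the genes with the largest log2 ratios. Other small RNAs, such as Scarna17 and Rn4.5s, were not left out. All measured cartilage genes entered by count, and at least 6 of them by name. The rule also asked for deposited intervals that do not overlap, a clause that was void because the files held none. Exceptions, named after their values were seen, were Runx2, Dlx5, Snap25, Mbp, Hoxb2, the Y-linked genes Kdm5d and Uty, Gm9846, Hbb-b1, Hbb-b2 and the genes that stand only in the closing section. Some genes that the rule names are not reported here.

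The gene lists were fixed before the data were examined. They were Odd-skipped genes (Osr1 and Osr2), cartilage, tendon and connective tissue, fibroblast matrix, bone formation, myogenic regulators, muscle contractile, epithelium, erythroid, endothelium, macrophage, neuron, Schwann lineage, cranial mesenchyme factors, mandible pattern, pharyngeal neighbour tissue, hedgehog, BMP and TGF-beta, WNT, FGF, cell cycle, cell cycle inhibitors and apoptosis, immediate early and heat shock, hypoxia and glycolysis, sex-linked, and mitochondrially encoded genes. Some genes stand in more than 1 list. Each list's median log2 ratio was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins with seed 1. A list was called higher or lower where its median lay outside the central 95% of these, as a description of these 2 libraries. Where the mean of a list was used instead, its band was the central 95% of the means of the random lists. A list with fewer than 3 measured members gave values only. Another 3 lists were added after the values were seen (retinoic acid pathway, Iroquois factors and small leucine-rich proteoglycans).

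The procedure was tested on simulated data before it was run on the libraries. For the comparison of mutant with control library, reads were drawn for every symbol with the status OK. Of the genes with at least 1 FPKM in the control library, 200 were changed by known factors. After drawing, 12296 genes had at least 1 FPKM in either simulated library. Of the genes changed 4-fold, 97% had a 2-fold or larger ratio, with a median fitted log2 ratio of 1.78. Of those changed 1.5-fold, 0% did. Counting noise alone took 15 unchanged genes to a 2-fold ratio, 5 of them with at least 5 FPKM.

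Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to a median log2 ratio of 0, quantile normalization, the TPM scale, thresholds of 1.5-fold and 3-fold, the highest row of each symbol, the mean of a list, 5 expression bins, and lists without their largest member. After the data were seen, 4 others were added, namely transcripts of at least 300 nt, genes with no overlap of another symbol, rows of any status, and random lists matched on length too. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.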

Results

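RNA of embryonic mouse tongue at embryonic day 12 was sequenced from 2 genotypes, with 1 library each. The control carried 1 conditional (floxed) allele of Osr1 beside a wild-type allele (Osr1f/+). The mutant carried the conditional allele over a null allele together with Wnt1cre, which removes the conditional allele in the neural crest lineage, the source of the tongue's connective tissue. Osr1 encodes a zinc finger transcription factor of the odd-skipped family. Tongues were pooled before RNA extraction, and there was no replicate library of either genotype. Every ratio below therefore compares 2 libraries, and no test between the genotypes could be made. The deposited values were FPKM of 28107 RefSeq transcript rows, here summed to 22072 gene symbols. Depth was estimated from the deposited coverage at about 18900000 mapped reads for the control library and 23100000 for the mutant library. A transcript of 1 kb with 3 reads would have 0.159 FPKM in the control and 0.130 FPKM in the mutant library.

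The first question was whether Osr1 itself differed between the libraries, which also checks the labels. Osr1 (NM_011859, mm9 chromosome 12, 9581248 to 9588306) had 56.8 FPKM in the control and 18.4 FPKM in the mutant library. The ratio was 0.325, with a 95% counting interval of 0.30 to 0.352 from about 2153 and 856 reads. The value covers the whole spliced transcript of 2011 nt. The labels do not say which part of the gene the conditional allele loses, so reads from the remaining part were included and the ratio is no measure of intact transcript. Cells outside the neural crest lineage keep the conditional allele in the mutant, and their share of the value was not tested. Osr2, the paralog of Osr1 (chromosome 15, 35225867 to 35233060), was higher in the mutant library, with 13.6 FPKM in the control and 17.3 FPKM in the mutant, a ratio of 1.27 (counting interval 1.13 to 1.44).

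The libraries were otherwise close. Of 12383 genes with at least 1 FPKM in either library, 98.5% differed by less than 1.5-fold, and the median log2 ratio was 0.0035. The values correlated across genes with r = 0.989 and rho = 0.992, where genes are not independent replicates. In the mutant library 58 genes were at least 2-fold higher and 33 were at least 2-fold lower, where these folds are of FPKM plus 1 and are smaller than the plain ratios of FPKM given for single genes. Of these, 48 and 24 had a transcript under 300 nt, whose FPKM rests on few reads. With the threshold of 5 FPKM and only named gene symbols, 8 of 8431 genes were at least 2-fold higher and 4 were lower on the same scale of FPKM plus 1. The higher genes still included the short or overlapping models Rps27, Scarna17, Atp6v0c-ps2 and Rn4.5s. Aspn among the higher genes and Rpl26 among the lower genes overlap other models too.

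Among named genes with at least 5 FPKM in either library, the 12 with the largest higher values were of several kinds. Mecom, a zinc finger transcription factor on chromosome 3 (29850218 to 29912126), had 12.6 FPKM in the control and 27.7 FPKM in the mutant library, a ratio of 2.21 (2.07 to 2.41). Irx1 and Irx2, neighbouring Iroquois homeobox genes on chromosome 13, had ratios of 2.24 (1.93 to 2.61) and 2.18 (1.83 to 2.62). Aspn, which encodes the matrix proteoglycan asporin, went from 4.30 FPKM in the control to 9.65 FPKM in the mutant library. Frzb, a secreted WNT inhibitor, had 5.83 and 12.3 FPKM, a ratio of 2.10 (1.85 to 2.4). Gsg1l had a ratio of 3.08 (2.54 to 3.78), from 1.73 FPKM in the control. Mpped2 and Mab21l2 had ratios of 1.95 (1.79 to 2.09) and 1.90 (1.73 to 2.09). The gene models of Aspn and Mab21l2 overlap those of other genes. The remaining 4 of the 12 genes with the largest higher values were Rps27, Scarna17, Atp6v0c-ps2 and Rn4.5s, all short or overlapping models. Rps27 was listed at 16.0 FPKM in the control and 583 in the mutant library, while Gm9846, a model on the same bases, was listed at 586 and 0.011 FPKM. Atp6v0c-ps2 overlaps another model as well and had 0.0016 FPKM in the control and 5.90 FPKM in the mutant library. Scarna17, a transcript of 62 nt, was listed at 0 in the control and rested on about 9 reads in the mutant. Rn4.5s, of 174 nt, rested on about 11 and 35 reads.

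Among named genes with at least 5 FPKM in either library, those with the largest lower values, after Osr1, included Thbs4. It is a thrombospondin of tendon and muscle connective tissue. Thbs4 had 41.5 FPKM in the control and 19.2 FPKM in the mutant library, a ratio of 0.461 (0.432 to 0.493). Mt2, a metallothionein, had a ratio of 0.463 (0.377 to 0.567). Ednrb, the endothelin B receptor, had a ratio of 0.538 (0.492 to 0.582). Tubb3, the neuronal beta-tubulin, had 6.33 FPKM in the control and 3.16 FPKM in the mutant library. H2afv, Ccdc3, Tmem204, Col23a1 and Naalad2 had ratios of 0.546, 0.519, 0.572, 0.644 and 0.609. Rpl26 (ratio 0.356) and Tmem204 overlap other gene models, so their reads were not assigned to 1 gene with certainty.

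The next question was whether genes of cartilage, a tissue that cranial neural crest can form, differed between the tongues. The list held 30 genes, of which 29 had a usable row and 21 reached 1 FPKM in either library, so the rest gave no ratio. Of the 21 measured cartilage genes, 19 were higher in the mutant library and 2 were lower. Their median ratio was 1.29-fold (log2 0.36), above the medians of all 10000 random lists matched on expression, whose central 95% ran from −0.06 to 0.07. Acan, Matn1 and Cytl1, at 0.811, 0.713 and 0.868 FPKM in the control, reached 1 FPKM only in the mutant library. Given the filter, these genes could only count as higher. Sox9, the regulator of chondrocyte fate (chromosome 11, 112643524 to 112649071), had 13.6 FPKM in the control and 23.1 FPKM in the mutant library, a ratio of 1.69 (1.57 to 1.82). Its partner Sox5 had a ratio of 1.63 (1.30 to 2.02), and Sox6 had 1.25 (1.08 to 1.42).

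The genes of the cartilage collagen fibril were higher together. Col2a1, the main collagen of cartilage (chromosome 15, 97806033 to 97835155), had 98.4 and 131 FPKM, a ratio of 1.33 (1.29 to 1.36). Col9a1 had 27.8 and 42.8 FPKM, a ratio of 1.54 (1.46 to 1.62), while Col9a2 had a ratio of 1.18 (1.11 to 1.25) and Col9a3 of 1.45 (1.33 to 1.59). Col11a1 and Col11a2 had ratios of 1.30 (1.24 to 1.36) and 1.41 (1.25 to 1.60). Of the non-collagen matrix genes, Matn4 had a ratio of 1.63 (1.44 to 1.84), Hapln1 1.43 (1.18 to 1.73) and Acan, which encodes aggrecan, 1.5 (1.18 to 1.90), the last from 0.811 FPKM in the control. Pth1r, a receptor of cartilage and bone, had a ratio of 0.886 (0.817 to 0.960). For Nkx3-2, Fgfr3, Cytl1 and Matn1 the counting interval of the ratio included 1. In the same libraries 6 of 6 measured Hox genes, listed for tissue behind the tongue, were higher in the mutant library. Hoxb2 was higher by less than its counting error (ratio 1.06, 0.814 to 1.38). Hoxa2 and Hoxa3 had 9.61 and 7.16 FPKM in the control library, so their RNA was not limited to the mutant dissection. Markers of blood, nerve and epithelium were lower. Xist was higher and the Y-linked genes were lower in the mutant library, as given below.

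**Figure D1:**
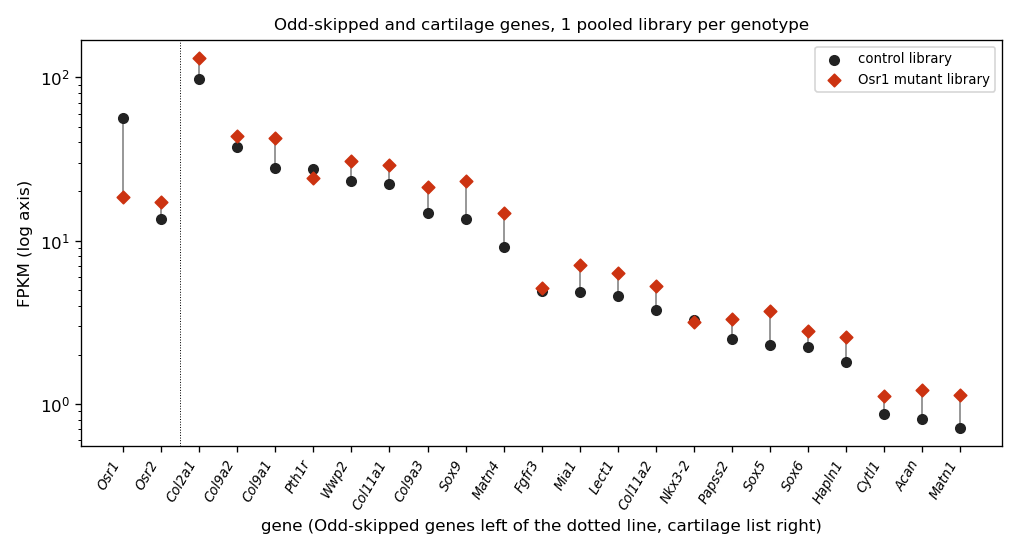
FPKM of Osr1, Osr2 and the 21 measured cartilage genes in the control and in the Osr1 mutant tongue library, 1 pooled library each, on a log axis. Of the cartilage genes, 19 lie higher in the mutant library, with Sox9 at 13.6 and 23.1 FPKM and Col2a1 at 98.4 and 131 FPKM.

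Tendon and connective tissue genes had a median log2 ratio of 0.15, with 8 of 12 higher and 4 lower, and 9997 of 10000 random lists lay below it. Scx, the transcription factor of tendon progenitors, had 23.8 and 33.7 FPKM, a ratio of 1.42 (1.27 to 1.58). Ogn, a small leucine-rich proteoglycan, had a ratio of 1.69 (1.54 to 1.86), and Col12a1 had 1.17 (1.11 to 1.24), whereas Thbs4 lay far lower, as given above. The median of the list was within the band over members of at least 5 FPKM, at 0.00072, and so was the median of genes without an overlapping model, 0.05. The mean of all its members, 0.09, was within the band of random means. General fibroblast matrix genes did not share the direction of the cartilage genes. Their median was −0.07, with 7 higher and 11 lower of 18, and 31 random lists lay below it. Without Dcn, however, the median of −0.03 was within the band, and the mean of −0.05 was within the band of random means. Dcn, which encodes decorin, had a ratio of 0.680 (0.603 to 0.765), Postn of 0.824 (0.799 to 0.858) and Lum of 0.830 (0.740 to 0.931), while Eln, which encodes elastin, had 1.25 (1.19 to 1.32).

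Bone formation genes, with a median of −0.05 over 7 genes, lay within the band of the random lists. Their mean of 0.17 had the opposite sign, and so did the median on the TPM scale, 0.10. Col1a1 had a ratio of 0.901 (0.883 to 0.919). Runx2, the regulator of osteoblast fate, and the homeobox gene Dlx5 were named after their values were seen. Runx2 had 1.79 and 3.83 FPKM, and Dlx5 had 1.62 and 3.63 FPKM.

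Skeletal muscle of the tongue derives from somites, outside the Wnt1-Cre lineage. By the genotypes, muscle cells still carried the null allele in the mutant and not in the control, whose label names no Wnt1cre. Myogenic regulators as a group lay within the band, with a median of −0.03, 7 higher and 10 lower of 17. Eya1, a coactivator of homeobox factors in muscle precursors, had a ratio of 1.52 (1.36 to 1.70), Six4 of 1.17 (1.07 to 1.28) and Eya2 of 1.14 (1.01 to 1.29). Lbx1 had 0.798 (0.597 to 1.05). Contractile genes had a slightly higher median of 0.08, with 19 higher and 8 lower of 27, and 9997 random lists lay below it, though the mean of 0.07 was within the band of random means. Tnnc1, Myl4 and Chrna1 had ratios of 1.17, 1.16 and 1.16, and Myh8, a perinatal myosin heavy chain, had 0.877.

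Markers of several other cell types were lower in the mutant library. All 9 measured erythroid genes were lower, with a median of −0.25 that lay below every one of the 10000 random lists. Hbb-y, an embryonic globin, had 1022 FPKM in the control and 827 in the mutant library, a ratio of 0.810 (0.789 to 0.831). Hba-x had a ratio of 0.841, Hbb-bh1 0.796 and Slc4a1 0.747. Reads of the near-identical globin copies Hbb-b1 and Hbb-b2 were not assigned to 1 gene with certainty. Hbb-b2, at 1.59 FPKM in the control, reached 1 FPKM only in that library, so given the filter it could only count as lower. For some of the 9 genes the counting interval included no difference, such as Hbb-b1 (log2 ratio −0.14, −0.41 to 0.10). Of 20 epithelial genes, 16 were lower and 4 higher, with a median of −0.10 and 5 random lists below it. The keratin genes Krt5, Krt15 and Krt14 had ratios of 0.796, 0.853 and 0.848, while Krt8 had 1.13 (0.958 to 1.34). Neuronal genes had a median of −0.26, with 7 of 12 lower, and no random list lay below it. Over 11 alternatives the neuronal median ran from −0.32 to −0.11. Its bootstrap interval over genes was wide, at −0.49 to 0.075. Crmp1 and Gap43 had ratios of 0.713 and 0.809, while Dcx, a microtubule protein of young neurons, had 1.32 (1.24 to 1.41). Snap25, a synaptic protein named after its values were seen, had 3.45 FPKM in the control and 0.239 in the mutant library. Genes of the Schwann lineage had a median of −0.10, with 8 of 11 lower and 119 random lists below it. The call was lost without the largest member, Mbp (−0.08), with a pseudocount of 0.1 (−0.10), over members of at least 5 FPKM (−0.10) and with quantile normalization (−0.098). Ngfr had a ratio of 0.849, Pmp22 of 0.930 and Itga4 of 0.954.

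Endothelial genes lay within the band, with a median of 0.02 that was −0.00065 after quantile normalization. Pecam1 and Erg had ratios of 1.24 and 1.27, and Sox18 and Kdr had 0.885 and 0.911. Macrophage genes, including Laptm5 with a ratio of 1.02, had a median of 0.11 within the band, with 9 of 13 higher. The 5 sex-linked genes had a median of −0.18, with 1 higher and 4 lower, 29 random lists below it and a mean of −0.10 within the band. Xist, the RNA of the inactive X chromosome, had 61.1 FPKM in the control and 86.1 in the mutant library, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had log2 ratios of −0.36, −0.35, −0.18 and −0.11. None of the 12 mitochondrially encoded genes had a row under the symbols searched.

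Transcription factors of facial mesenchyme were split, with 21 higher and 19 lower of 40. Their median of 0.01 lay within the band and was −0.02 after quantile normalization. Tbx2 had 8.65 and 14.8 FPKM, a ratio of 1.71 (1.55 to 1.89), and Foxc1 had a ratio of 1.43 (1.30 to 1.58). The forkhead genes Foxd1 and Foxd2 were lower, with ratios of 0.747 (0.705 to 0.791) and 0.661 (0.591 to 0.739). Genes that pattern the mandible had a median of 0.06 within the band, with 8 of 13 higher. Hand1 and Cited1 had ratios of 0.758 and 0.749. Genes of tissue behind the tongue had a median of 0.23, above all 10000 random lists, with 7 of 10 higher, while their mean of 0.12 was within the band. Hoxa2, Hoxa3 and Hoxb3, which pattern the second and later pharyngeal arches, had ratios of 1.18 (1.02 to 1.37), 1.23 (1.07 to 1.41) and 1.41 (1.23 to 1.65), and Nkx2-5, a factor of heart and pharynx, had 0.746 (0.646 to 0.861).

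Among signalling pathways, BMP and TGF-beta genes had a median of 0.11, with 16 of 26 higher, and 9996 random lists lay below it, while the mean of 0.04 was within the band. Gdf10, Tgfb3 and Bmp5 had ratios of 1.37, 1.28 and 1.32, and Fst, which encodes the inhibitor follistatin, had 0.697 (0.630 to 0.770). The hedgehog list lay within the band at −0.04, with 10 of 15 lower. Its ligand Shh and the target gene Gli1 had ratios of 0.757 (0.645 to 0.884) and 0.777 (0.736 to 0.821), and the coreceptor Boc had 1.29 (1.2 to 1.38). WNT genes lay within the band with a median of −0.02 and a mean of 0.02. Wnt6 had a ratio of 0.633, and Dkk2 and Lgr5 had 1.45 and 1.31. FGF genes had a median of 0.03 within the band. Fgf18 and Etv4 had ratios of 0.677 and 0.825, and Fgfr2 and Spry2 both had 1.21.

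Cell cycle genes were slightly lower as a group, with 19 of 23 lower, a median of −0.09 and 1 random list below it. The largest differences were those of Bub1, Aurkb, Rrm2 and Cdc20, with ratios of 0.838, 0.870, 0.896 and 0.900. Cell cycle inhibitors and apoptosis genes lay within the band at 0.02. Trp53inp1 had a ratio of 1.24, Cdkn1a 1.11, Mdm2 1.09 and Ccng1 1.06. Immediate early and heat shock genes lay within the band at −0.07, with Jun at a ratio of 1.23 and Dusp1 at 1.19, and with Ier2 and Dnajb1 at 0.825 and 0.899. Hypoxia and glycolysis genes lay within the band at 0.02, where Egln3, an oxygen-sensing hydroxylase, had a ratio of 1.69 (1.44 to 2.00), Vegfa 1.10, Ldha 1.07 and Ero1l 0.908.

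**Figure D2:**
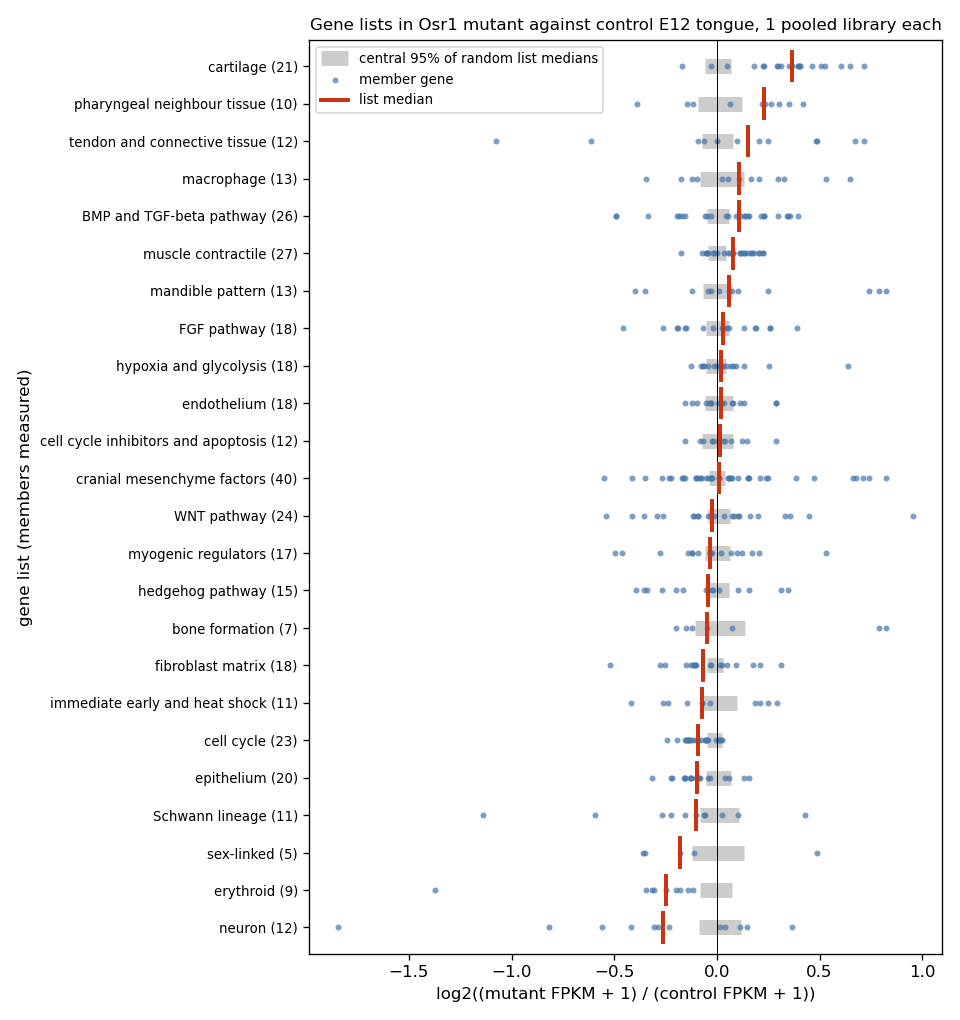
Log2 of mutant over control FPKM, each plus 1, for the measured members of 24 gene lists. Points are genes, red bars the list medians, and grey bars the central 95% of the medians of 10000 random lists matched on expression. Cartilage has the highest median at 0.36 and the neuron list the lowest at −0.26.

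Across the 24 lists with at least 3 measured members, 12 had a median outside the central 95% of their random lists, with 5 above and 7 below. By chance 1.2 lists would be expected outside if genes varied independently. Members of a list are expressed in the same cells, so random lists of unrelated genes understate how far a list moves when the cell make-up of a pool shifts.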

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

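The settings for transcript length, overlap, status and length matching were chosen after the data were seen, and the others before. The numbers of genes past a fold threshold moved most. Of genes higher in the mutant library, 58 in the main analysis, there were 10 with a pseudocount of 5, 18 with a filter at 5 FPKM, 111 on the TPM scale, 111 at 1.5-fold, 26 at 3-fold, 10 among transcripts of at least 300 nt and 15 among genes without an overlapping model. Of genes lower, 33 in the main analysis, there were 59 with a pseudocount of 0.1, 3 with a pseudocount of 5, 7 with a filter at 5 FPKM, 65 on the TPM scale, 72 at 1.5-fold, 10 at 3-fold, 64 with the highest row of each symbol, 9 among transcripts of at least 300 nt and 9 among genes without an overlapping model. The TPM scale multiplies the FPKM by about 3.27, so a pseudocount or filter of 1 weighs less there. The log2 ratio of Osr1 was −1.40 with a pseudocount of 5, against −1.57.

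Cartilage stayed above its band in all 11 alternatives, with medians of 0.23 to 0.46. Of 132 alternatives for the 12 lists outside the band, 119 left the call and its direction in place, and 13 brought the list inside. With the mean of members, set against random means, these were tendon (0.089), fibroblast matrix (−0.052), muscle contractile (0.073), pharyngeal neighbour tissue (0.12), BMP and TGF-beta (0.044) and sex-linked genes (−0.10). Over members of at least 5 FPKM they were tendon (0.00072) and Schwann lineage (−0.10). Without the largest member they were fibroblast matrix (−0.031) and Schwann lineage (−0.083). Schwann lineage also came inside with a pseudocount of 0.1 (−0.10) and with quantile normalization (−0.098), and tendon without overlapping genes (0.048). The cause was not tested. Of 130 alternatives for the 12 lists within the band, 1 brought a list outside, macrophage without overlapping genes (0.14), and 10 moved the median across 0. Of 640 alternatives for 128 gene ratios, 617 moved the log2 ratio by no more than the distance from the middle of its counting interval to either end, or had an interval open at one end, and 23 moved it further. No direction of a called result reversed.

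The alternative with deposited intervals that do not overlap was not run, since the files used here held none. There was no replicate to leave out. No paired analysis was possible because each genotype had 1 library. Depth limits mainly genes near 1 FPKM and short transcripts, where 3 reads on 1 kb are 0.159 FPKM in the control library.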

Other observations

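The tests of explanations in this part, and the lists of Iroquois factors, small leucine-rich proteoglycans and retinoic acid pathway genes, were chosen after the values were seen, while the other lists were fixed before. Besides Irx1 and Irx2, the other measured Iroquois gene, Irx3, had 1.10 FPKM in the control and 2.32 in the mutant library, a ratio of 2.11 (1.46 to 3.04). The 3 Iroquois factors had a median log2 ratio of 0.95, but 2 of them had led to the choice of the list, so no rank among random lists is given. Of the low-level homeobox genes of the face, Dlx6 had 0.827 and 2.06 FPKM and Msx2 0.860 and 1.97 FPKM. Both reached 1 FPKM only in the mutant library, and Dlx5 was higher as given above. Others differed little, with Msx1 at 2.21 and 2.24 FPKM, Dlx3 at 1.71 and 1.85 and Alx1 at 3.47 and 3.50. Dlx1 had 3.28 and 3.44 FPKM, and Dlx2 had 3.71 and 3.47 FPKM. Mgp, the matrix Gla protein that inhibits calcification of cartilage and vessels, had 16.2 and 26.9 FPKM, a ratio of 1.66 (1.39 to 1.99). Sertad4 had a ratio of 1.69 (1.62 to 1.79) and Pamr1 of 1.91 (1.68 to 2.18).

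The small leucine-rich proteoglycans, secreted proteins that bind collagen, went both ways. Their median was 0.33 over 7 genes, with a bootstrap interval over genes of −0.25 to 0.72. No rank among random lists is given, since Aspn and Ogn had led to the choice of the list. Aspn, Ogn, Fmod and Podn were higher in the mutant library, with log2 ratios of 1.01, 0.72, 0.67 and 0.33. Dcn, Lum and Bgn were lower, with −0.52, −0.25 and −0.06, so the list did not move as 1 block.

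Cartilage genes were higher in the mutant library, with a median of 0.36, and 3 other explanations than the genotype were weighed. Erythroid, neuronal and epithelial markers were lower, with medians of −0.25, −0.26 and −0.10. If nothing but a loss of these cells were at work, general mesenchymal genes would be higher by about as much as cartilage genes. The fibroblast matrix median was −0.067 (95% bootstrap interval over genes −0.12 to 0.04), without such a rise. These matrix genes are expressed in the mesenchyme that lost Osr1, however. A lower level of their own could hide a rise, so the values cannot exclude this explanation. Tissue behind the tongue in the mutant dissection may have added cartilage RNA, but the values cannot decide it. The 6 Hox genes of the pharyngeal list had a median of 0.28 (0.14 to 0.39). They were set apart after all were seen to be higher, so an interval above 0 was fixed in advance. The whole list had a bootstrap interval of −0.12 to 0.30. Of its 4 other measured genes only Nkx2-5 differed beyond counting error, and was lower (−0.39). Mandible tissue with Meckel's cartilage cannot be told apart from the genotype, because only 5 mandible pattern genes were low enough in the control to show it. Their median of 0.74 had an interval of 0.01 to 0.82. That median is the value of Dlx6, which reached 1 FPKM only in the mutant library and so could only count as higher. All 13 measured genes of the list had a median of 0.06 (−0.05 to 0.25). A higher level of cartilage genes in Osr1 mutant mesenchyme stays open as well, and was not tested, since genotype and library are the same.

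Rps27 had the largest log2 ratio with a pseudocount of 1 among the named genes, and its model lies on the same bases of chromosome 3 as Gm9846. The summed FPKM of both models was 602 in the control and 583 in the mutant library, a log2 ratio of −0.047. The difference is thus consistent with reads given to 1 model in the control and to the other in the mutant library. An effect of genotype was not tested.

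The 4 Y-linked genes pooled had a log2 ratio of −0.34 (counting interval −0.43 to −0.25), and Xist had a ratio of 1.41 (1.38 to 1.43). These values are consistent with more RNA of female embryos in the mutant pool. How far a different sex mix reached other genes was not tested, and the labels give no sex.

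Rarb, a retinoic acid receptor, and Aldh1a2, which makes retinoic acid, had ratios of 1.77 (1.57 to 2.01) and 1.45 (1.34 to 1.58) in the mutant library. The hypothesis that retinoic acid pathway genes were higher as a group was tested on the other 13 measured members. Their median log2 ratio was −0.029, with 2022 of 10000 random lists below it, which speaks against a rise of the whole group. With Rarb and Aldh1a2 the median was 0.02. The median does not measure the activity of the pathway. Among the other members, Dhrs3 and Rdh10 had ratios of 1.35 and 1.32. Cyp26a1, Cyp26c1 and Aldh1a3 had ratios of 0.534 (0.365 to 0.783), 0.202 (0.104 to 0.388) and 0.515 (0.399 to 0.662). These latter genes were at low levels, with 2.17, 1.75 and 2.58 FPKM in the control library.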
